A study of Mus musculus with 12 samples.

How the data were processed

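Gene expression was measured in immortalized tumor-initiating cells of the mouse on Illumina Mouse WG-6 v2.0 BeadChips, which carry oligonucleotide probes on beads and are read in 1 colour. The 12 arrays were 3 of cells kept in hypoxic stem cell conditions, 1 for each of days 1 to 6 after transfer to normoxic standard conditions, and 3 for day 7. Groups, days and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled cRNA was made with an amplification kit for Illumina arrays. The scanner software and the summarization of beads into probes were not given in the sources used here.

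The deposited table of all arrays held, for each of 45281 probes, a log2 signal and a detection p-value per array. The deposited log2 signals were taken, from the values, to be neither background-corrected nor normalized between arrays, with medians of 6.74 to 6.94. Column names of the log2 signals equalled the description labels of the samples and were used to assign them. The deposited detection p-value columns, whose steps were 1 in 936, carried no sample names per the file headers. The deposited p-values did not belong to the signal column printed beside them. In 0 of 12 cases did the neighbouring column order the signals, with 16884 to 18174 inversions, whereas each of the 12 signal columns was ordered exactly by 1 of the p-value columns, which was then used for it.

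The authors' processed value table held detection p-values in 6 of its columns and log2 signals in the other 6, with column medians near 4.95. By rank correlation with the signals described above, of those 6 signal columns only 1 held the array of its own label, and the others held arrays named differently above, so the sample names of both deposited tables conflict. After neqc, values differed from these by at most 0.0236 on the log2 scale, so the authors' scale is log2, uncentred, and the method is not given in the sources used here. That table was not used for any result. The 6 arrays it holds (hypoxic replicate 3, days 4 to 6, and day 7 replicates 2 and 3) are called set a and the other 6 set b. The order of the detection p-value columns keeps the same sets together, columns 1 to 6 belonging to arrays of set a and 7 to 12 to arrays of set b. Both deposited tables thus point to 2 groups of 6 arrays handled together. That these are batches or chips is inferred, not stated by any label.

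Signals were returned to the linear scale and processed with neqc of limma, which fits a normal plus exponential background model using the detection p-values, adds an offset of 16, normalizes by quantiles and takes log2. A probe was kept if its detection p-value lay below 0.05 on at least 3 of the 12 arrays, which left 18561 probes. Names came from the platform annotation supplied with the series. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 were unnamed here, and 0 symbols changed when updated through Entrez identifiers against RefSeq genes of assembly GRCm38.p6. Of the kept probes, 16023 had 1 gene and 2538 did not. Each of the 10365 genes tested was represented by the kept probe with the highest mean over all arrays. For 3872 genes more than 1 probe was kept. Tested singly for day 7 against hypoxic cells, the probes of 149 of these genes passed the threshold in opposite directions, and those of 1336 all passed in 1 direction.

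A limma linear model with a mean for each of the 8 groups was fitted to all 12 arrays, and variances were moderated with eBayes. Only the hypoxic and day 7 triplicates carry residual spread, with 4 residual degrees of freedom. Contrasts were day 7 against hypoxic, and the mean of days 1 to 3 against hypoxic, which takes single arrays to vary like the triplicates. A slope per day was fitted over the 9 normoxic arrays, with 7 residual degrees of freedom. Tests were 2-sided with Benjamini-Hochberg adjustment, and an adjusted p below 0.05 is called past the threshold. The terms rose and fell mark such calls. No single day from 1 to 6 was tested. For each normoxic array, genes at 2-fold or more from the mean of each pair of hypoxic arrays were counted, with each left-out hypoxic array against the other pair as background. The precision of every value is limited by the number of arrays.

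Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 24 lists with at least 5 measured members. Camera with an estimated correlation and fry were run beside it. The estimated version rests on the residual degrees of freedom, 4 for the contrasts and 7 for the slope, which leaves it little power. It passed 0 lists in every comparison and was not run on the simulated data, so a call lost under it stays undecided. The 28 lists held 749 entries, of which 695 matched a named probe (11 of them through a synonym) and 563 were measured. They covered HIF targets, glycolysis, sterol and fatty acid synthesis, metalloproteases with their inhibitors, cathepsins and lysosomal genes, extracellular matrix, luminal, basal and stem cell genes, epithelial-mesenchymal transition, mitosis, DNA replication, serum-response, YAP/TEAD, ATF4, endoplasmic reticulum chaperone, NRF2, interferon-response, oxidative phosphorylation, chemokine and NF-kB, p53 and TGF-beta targets. Macrophage, fibroblast, endothelial, adipocyte and lymphocyte markers made up the remaining 5 lists. Synonym matching was corrected after values were seen, when current symbols of the glycolysis list were found matched to other genes, and no list call changed. For single days, a list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description only.

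Genes were named by a rule: Mmp14 in each comparison, the 6 largest rises and 6 largest falls on day 7 among called genes whose hypoxic and day 7 values did not overlap, the member of each list with the largest rise and the largest fall, and the 4 largest rises and falls of the early contrast and of the slope. Clone and predicted-gene names were left out, and metalloprotease list members could be named whether called or not. Groups, the 3 comparisons, the lists, this rule and most alternatives were fixed before the data were examined. The contrast of day 7 against days 1 to 3, the list tests of the early contrast, and the genes highest or lowest on days 1 to 3 were added after the data were seen. The last were genes whose early mean lay above, or below, both hypoxic and day 7 means, with the larger of the 2 p-values adjusted.

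A gene was taken as not above background in a group if the probe used for it was detected on no array of that group, and its change is then given as at least N-fold. For genes named with such a bound, no other named probe was detected in that group either. This bound sets the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest normalized signal among detected probes and the probe's own signal. No fold is given where neither group was above background or the bound lay below 1. For the contrasts against hypoxic cells, medians of lists were also taken with such members at their bound.

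The procedure was tested on simulated data with the observed means and spreads, in which 66 or 67 of the 10365 genes were shifted at each of 3 sizes and the mitotic list by 1, and that list was called in each comparison. Shifts of 2 on the log2 scale were recovered for 92.4% of the changed genes for day 7 against hypoxic, 90.9% for days 1 to 3 against hypoxic and 89.4% for the slope across the days. Shifts of 1 were recovered for 55.2%, 58.2% and 68.7%, and shifts of 0.5 for 5.97%, 2.99% and 20.9%. False calls made up 7.26%, 5.04% and 3.57% of calls. In the data 59.7%, 54.9% and 35.5% of genes passed, so the adjusted threshold there is laxer and these rates do not carry over. Errors were drawn independently for each gene, so the list call does not test the assumed inter-gene correlation.

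Alternatives covered the background correction and normalization, the detection filter, the treatment of several probes, the variance model, array weights, the arrays in the fit, the replicate number as a block, the scale of time, the early window, the set test and each array left out in turn. Background fitted without detection p-values, scaling on probes detected on all arrays, the set as a block and each set alone were added after the data were seen. Versions were R 4.3.3, limma 3.58.1, the R package data.table (version 1.17.8), Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.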

Results

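Expression was profiled in immortalized tumor-initiating cells, mouse mammary tumour cells selected for the capacity to seed tumours, in 2 culture states. Hypoxic stem cell conditions were serum-free mammary stem cell medium with 2% Cultrex, a basement membrane preparation, at 3% oxygen, with 3 arrays. Normoxic standard conditions were DMEM-based medium at 21% oxygen for 1 to 7 days, with 3 arrays for day 7 and 1 array for each earlier day. Oxygen and medium changed together, so no comparison separates them. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. For days 1 to 3 against hypoxic cells, SEs and p-values use the spread of the hypoxic and day 7 arrays only. They hold no difference between the early days. Between 34.3% and 37.7% of the 45281 probes were detected per array. Sample names follow the column names of the deposited signal table, with which the names in the authors' processed table conflict. Under the names used, hypoxic arrays correlated with one another across genes, after centring each gene, at 0.89 to 0.90 and day 7 arrays at 0.59 to 0.70. The median SD of a gene was 0.17 over the hypoxic and 0.19 over the day 7 arrays on the log2 scale. The first principal component held 56.0% of the variance and parted hypoxic from normoxic arrays, and the second, with 22.8%, ran from day 1 to day 7.

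**Figure D1:**
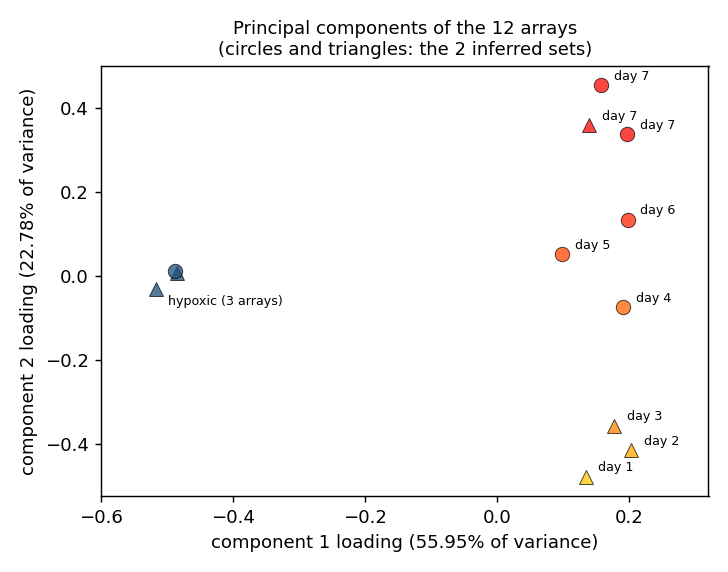
Loadings of the 12 arrays on the first (x axis, 56.0% of variance) and second (y axis, 22.8%) principal components, in arbitrary units, with circles for set a and triangles for set b. Hypoxic arrays lie between -0.518 and -0.486 on the first component, and all normoxic arrays lie above 0.

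The first comparison asked how cells after 7 days in normoxic standard conditions differed from cells kept in hypoxic stem cell conditions. Mmp14, the membrane-anchored matrix metalloprotease named in the title of the series, fell by 1.48 on the log2 scale (2.79-fold, SE 0.13, limma adjusted p = 8.00e-05), from 13.06 ± 0.06 in hypoxic cells to 11.58 ± 0.14 on day 7 (mean ± SD, n = 3 each), and was lower on 3 of 3 day 7 arrays than on any hypoxic array. The lists of mitosis, DNA replication, sterol synthesis, epithelial-mesenchymal transition, and chemokine and NF-kB targets passed with higher medians on day 7. Those of HIF targets, glycolysis, ATF4 targets and endoplasmic reticulum chaperones passed with lower medians. With an estimated correlation none of these list calls held (adjusted p 0.114 to 0.539). That test has 4 residual degrees of freedom and passed 0 lists in any comparison, so it does not decide these calls. The largest rise was that of Saa3, an acute-phase serum amyloid, by 6.28 (77.6-fold), and the largest fall that of Prelp, a matrix proteoglycan, by -5.86 (58.1-fold).

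Past the threshold were 6184 of 10365 genes (59.7%), of which 2688 were higher and 3496 lower on day 7, and 3084 of them (1423 higher, 1661 lower) differed by at least 2-fold. Hypoxic and day 7 values did not overlap for 6846 genes (66.0%), where chance gives 10%. With the inferred sets as a block, 5801 genes passed, and within set a and set b alone 2626 and 4533. Set a holds 1 hypoxic and set b 1 day 7 array, so each count within a set rests on 1 residual degree of freedom and takes the lone array to vary like the others. The median gene lay at -0.11 on the log2 scale, and moved to -0.31 when arrays were shifted to a common median and to 0.09 when that median was taken over probes detected on all arrays. The share of called genes that were higher was 43.5%, against 31.8% with the shift to a common median and 52.4% with that over probes detected on all arrays. Changes given here are on the main scale, and no called list turned its direction under another scaling. Of lists that did not pass, metalloproteases (-0.14) and stem cell genes (-0.19) had medians below 0 with the shift to a common median, and the lysosomal (0.10), basal (0.145), serum-response (0.26), TGF-beta (0.21) and fatty acid (0.14) medians lay above 0 with scaling on probes detected on all arrays.

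Besides Saa3, the largest rises were of Cthrc1, a secreted collagen triple helix protein (at least 37.8-fold), the cysteine protease inhibitor Stfa1 (at least 28.4-fold), the chemokine Ccl9 (5.47 ± 0.17 SE, detected on 1 of 3 hypoxic arrays), the prolactin-family hormone Prl2c3 (5.46 ± 0.26) and the steroid dehydrogenase Akr1c18 (5.34 ± 0.22). Stfa1 and Prl2c3 have near-identical paralogs, so that cross-hybridisation leaves the source of their signal uncertain. Cthrc1 and Stfa1 were not above background on any hypoxic array. Besides Prelp, the largest falls were of Tenm4, a teneurin of the cell surface (-5.48 ± 0.12), the glutathione transferase Gsta3 (-4.53 ± 0.23), the carbonic anhydrase Car12 (-4.49 ± 0.21), the ribonuclease Rnase1 (-4.37 ± 0.35) and Tril, a regulator of Toll-like receptor signalling (-4.13 ± 0.24). Rnase1 and Tril were each detected on 2 of 3 day 7 arrays. Adjusted p for these 12 genes ran from 4.20e-06 (Tenm4) to 6.19e-05 (Rnase1). Another probe did not reach the threshold for Tenm4 (-0.35, adjusted p = 0.237), of whose 3 probes 2 passed, and for Gsta3 (-0.59, adjusted p = 0.0982).

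Metalloproteases and their inhibitors moved in both directions. Of 23 measured, 8 rose, 4 fell and 11 did not pass, with the same counts adjusted over the list alone, and the list test was not passed (median 0.08, adjusted p = 0.197). The stromelysin Mmp3 rose by 4.82 ± 0.18 (adjusted p = 1.13e-05, detected on 1 of 3 hypoxic arrays), the inhibitor Timp1 by 4.32 ± 0.18 (1.13e-05) and the gelatinase Mmp2 by 1.13 ± 0.15 (0.000568). Macrophage elastase Mmp12 rose at least 11.7-fold (1.60e-05) and stromelysin Mmp10 at least 4.16-fold (1.49e-05), neither being above background on any hypoxic array. The aggrecanase Adamts4 (1.34), Adam12 (1.19) and Adamts9 (0.70) rose too. Besides Mmp14, the falls were of stromelysin Mmp11 (-1.32), Timp3 (-1.04) and Timp2 (-0.74). The collagenase Mmp13 stood at -0.79 ± 0.30 (adjusted p = 0.0553) and passed under 9 of its 20 alternatives (adjusted p down to 0.00767), while Mmp9, Mmp24, Mmp28, Adam8, Adam9, Adam10, Adam15, Adam17, Adamts1 and Reck did not pass on the probes used. Under alternatives Mmp9, rising, and Adam17, falling, passed in 3 each (limma adjusted p down to 0.00751 and 0.00638), and Adam10, falling, in 1 (0.0320). Another probe passed for Adam15 (1.34) and, in the opposite direction, for Adamts1 (-0.75, adjusted p = 0.00295). Another probe pointed the other way for Adam12 (-0.24, adjusted p = 0.420) and Timp3 (0.35, adjusted p = 0.209), and the call of Adamts9 ended in 5 of its alternatives, among them the omission of hypoxic replicate 2 or 3 or of day 7 replicate 1 or 3 (adjusted p 0.0515 to 0.0741) and the shift to a common median (0.30, adjusted p = 0.293). Calls also ended with the mean over probes for Adam12 (adjusted p = 0.0716) and Timp3 (0.0547) and with scaling on probes detected on all arrays for Timp2 (0.112).

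**Figure D2:**
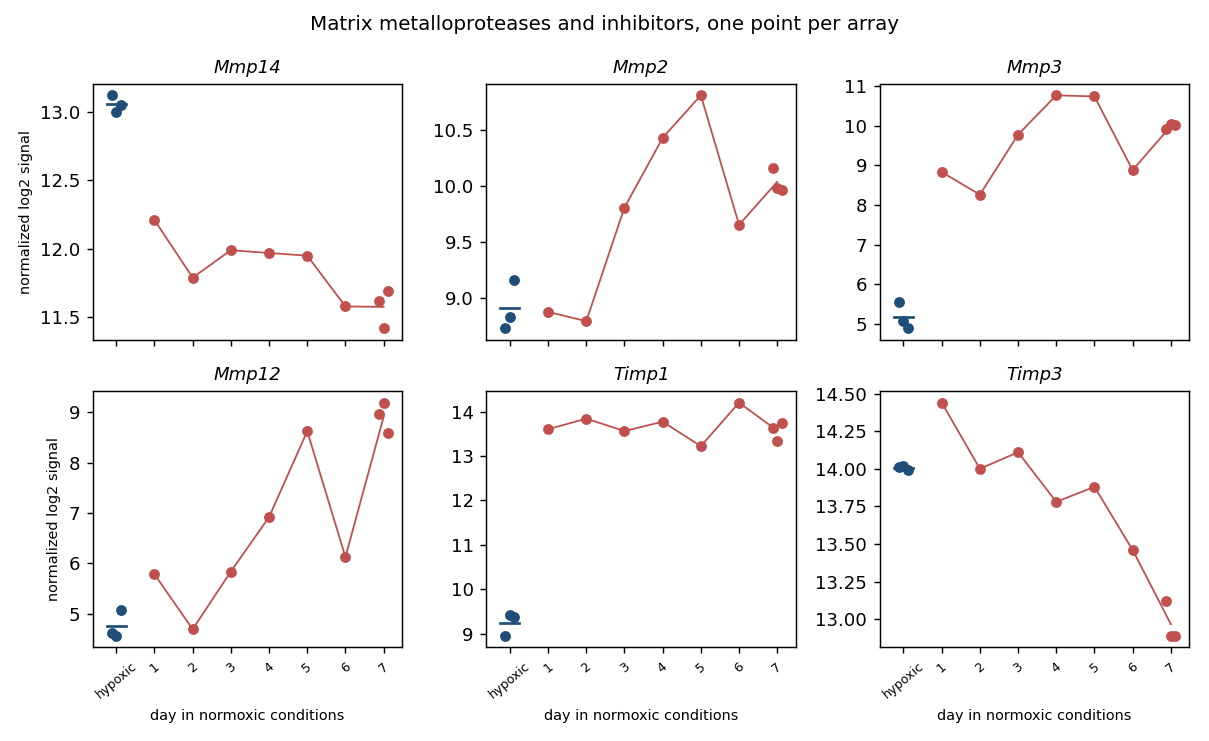
Normalized log2 signal (y axis) of 6 genes in hypoxic cells (blue) and by day in normoxic conditions (red, x axis), 1 point per array, with bars for the hypoxic mean and lines through daily means. Mmp14 starts at 13.06 and ends at 11.58, Timp1 rises from 9.25 to 13.57, and Timp3 falls from 14.01 to 12.97 on the probe shown although another of its probes does not.

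Genes of cell division were higher on day 7. Of 25 mitotic genes 24 rose and 0 fell (median 1.95, adjusted p = 1.91e-11, adjusted p = 0.156 with an estimated correlation), led by Birc5, the survivin gene, at 3.57 ± 0.17. Of 33 DNA replication genes 31 rose and 0 fell (median 1.77, adjusted p = 1.91e-11, adjusted p = 0.187 with an estimated correlation), led by the ribonucleotide reductase subunit Rrm2 at 4.66 ± 0.19, detected on 1 of 3 hypoxic arrays and at 0.97 on another probe. Both counts were the same adjusted over the list alone.

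Genes of the hypoxia response and of sugar metabolism were lower on day 7. Among 25 HIF targets, genes induced by the hypoxia-inducible factors, 19 fell and 3 rose (20 and 3 adjusted over the list alone), with a median of -1.08 (adjusted p = 0.000795, adjusted p = 0.187 with an estimated correlation). Ndrg1, a stress-responsive gene, fell most (-3.91 ± 0.24), and Angptl4, a secreted lipase inhibitor, rose most (3.97 ± 0.31). Of 16 glycolysis genes 13 fell and 0 rose, likewise adjusted over the list alone (median -0.86, adjusted p = 0.000168, adjusted p = 0.148 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, fell most (-2.28 ± 0.11). Of 33 oxidative phosphorylation genes 21 rose and 3 fell, likewise adjusted over the list alone (median 0.50, adjusted p = 0.000168, adjusted p = 0.114 with an estimated correlation). The extremes were Cox7b, a cytochrome oxidase subunit (2.35 ± 0.23), and Ndufv1, a complex I subunit (-0.63 ± 0.14), whose call ended under the shift to a common median over probes detected on all arrays (adjusted p = 0.400).

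Sterol biosynthesis genes rose, 14 of 18 with 0 falling (15 adjusted over the list alone), at a median of 0.97 (adjusted p = 4.64e-06, adjusted p = 0.148 with an estimated correlation). Mvk, the mevalonate kinase, led with 3.62 ± 0.12 and was detected on 1 of 3 hypoxic arrays. Of 11 fatty acid synthesis genes 4 rose and 2 fell, likewise adjusted over the list alone, and the list did not pass (adjusted p = 0.679), with a median of -0.0074 against a mean of 0.10 and a test pointing up. Its extremes were the desaturase Fads2 (0.90 ± 0.15) and the elongase Elovl5 (-0.49 ± 0.12), whose call ended under the same scaling as that of Ndufv1 (adjusted p = 0.788).

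ATF4 targets and chaperones of the endoplasmic reticulum, 2 programmes of the cellular stress response, were lower on day 7. Of 28 ATF4 and amino-acid starvation genes 23 fell and 1 rose (median -1.03, adjusted p = 0.000168, adjusted p = 0.539 with an estimated correlation), from the glycoprotein hormone Stc2 (-2.77 ± 0.29) to the serine synthesis enzyme Phgdh (0.73 ± 0.17). Of 20 chaperone genes 16 fell and 1 rose (median -1.38, adjusted p = 6.15e-05, adjusted p = 0.114 with an estimated correlation). Here the oxidoreductase Ero1b was at least 7.59-fold lower and not above background on any day 7 array, and the translocon subunit Sec61b rose by 1.03 ± 0.16. Both counts held adjusted over the list alone. Of 27 NRF2 antioxidant genes 11 rose and 5 fell, likewise adjusted over the list alone (median 0.26, adjusted p = 0.206, or 0.0271 with every probe on its own). The carbonyl reductase Cbr3 rose most (1.98 ± 0.19) and Gsta3 fell most (-4.53 ± 0.23, -0.59 on another probe). Of 24 measured members of the p53 list 5 rose and 8 fell (4 and 8 adjusted over the list alone, median -0.27, adjusted p = 0.449). The extremes of this list were the cell cycle inhibitor locus Cdkn2a (0.76 ± 0.12) and Trp53inp1 (-1.93 ± 0.14).

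Among 30 chemokine and NF-kB target genes 15 rose and 6 fell, likewise adjusted over the list alone (median 0.75, adjusted p = 0.000795, adjusted p = 0.192 with an estimated correlation), with Saa3 and the adhesion molecule Icam1 (-1.56 ± 0.21) at the ends. Of 29 interferon-response genes 8 rose and 4 fell on day 7 (7 and 4 adjusted over the list alone, median 0.29, adjusted p = 0.353), and the list passed only without day 7 replicate 3 (median 0.48, adjusted p = 0.0352). The guanosine triphosphatase Ifi47 rose by 3.28 ± 0.19, and Oas2, an oligoadenylate synthetase, was at least 1.30-fold lower, not above background on any day 7 array, with a call that ended under scaling on probes detected on all arrays (adjusted p = 0.0588). Beside these groups, macrophage and lymphocyte markers were mostly not measured. Of 18 macrophage markers, 17 of them with a named probe, 3 were measured (Lyz1, Cd14 and Mpeg1) and 1 was detected on all day 7 arrays. That was Cd14, the lipopolysaccharide co-receptor, which rose by 1.87 ± 0.18. Of 17 lymphocyte markers, 11 with a named probe, 1 was measured (Cd4), and 0 were detected on all hypoxic or all day 7 arrays. These lists were too small to test.

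Genes of epithelial-mesenchymal transition rose in 15 of 24 cases and fell in 5, likewise adjusted over the list alone (median 1.23, adjusted p = 0.000795, adjusted p = 0.148 with an estimated correlation). Of those 24, 13 are also held by another list. The glycoprotein Fstl1 rose most (5.16 ± 0.27, detected on 2 of 3 hypoxic arrays) and the transcription factor Snai2 fell most (-1.28 ± 0.20). Fibroblast markers moved with this group. Of 9 measured, 5 of them shared with other lists, 6 rose and 1 fell, likewise adjusted over the list alone (median 0.80, adjusted p = 0.0105, adjusted p = 0.192 with an estimated correlation), and 4 were detected on all hypoxic arrays against 7 on all day 7 arrays. The proteoglycan Dcn rose by 3.76 ± 0.17, and the receptor Pdgfra fell by 0.45 ± 0.13 (adjusted p = 0.0209), a call that ended in 5 alternatives, among them without hypoxic replicate 2 (adjusted p = 0.0570) or 3 (0.0764) or day 7 replicate 1 (0.0675). Of 26 extracellular matrix genes 11 rose and 8 fell, likewise adjusted over the list alone (median 0.29, adjusted p = 0.236), from the thrombospondin Thbs2 (3.88 ± 0.16, detected on 1 of 3 hypoxic arrays) to the laminin chain Lama5 (-3.51 ± 0.23). Of 22 TGF-beta targets 7 rose and 7 fell, likewise adjusted over the list alone (adjusted p = 0.659), with a median of -0.038 (0.036 with members at their bound) against a mean of 0.38 and a test pointing up. Its extremes were Id3, an inhibitor of basic helix-loop-helix factors (5.05 ± 0.27, detected on 1 of 3 hypoxic arrays), and the matricellular protein Ccn2 (-1.30 ± 0.12).

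Lineage lists did not pass. Of 23 luminal epithelial genes 5 rose and 13 fell (5 and 14 adjusted over the list alone, median -0.62, adjusted p = 0.117), from the aldehyde dehydrogenase Aldh1a3, at least 12.1-fold higher and not above background on any hypoxic array, although another probe gave only 0.66 (adjusted p = 0.0302), to the epithelial splicing regulator Esrp1 (-2.14 ± 0.14). Of 20 basal and myoepithelial genes 6 rose and 8 fell (median -0.064, adjusted p = 0.871), with the 14-3-3 protein Sfn at 2.97 ± 0.30, although another probe gave -0.10 (adjusted p = 0.571), and the basal regulator Trp63 at -1.81 ± 0.16. Stem cell and tumour-initiating cell genes were split, with 9 of 21 rising and 9 falling (median 0.08, adjusted p = 0.659), between Id3 and the receptor Notch1 (-2.37 ± 0.17). Serum-response genes rose in 8 and fell in 7 of 25 cases (median -0.046 with a test pointing up, adjusted p = 0.842), from the actin-binding protein Tagln (at least 1.65-fold higher, not above background in hypoxic cells) to the serum response factor Srf (-1.34 ± 0.13). Of 17 YAP/TEAD targets 4 rose and 7 fell (median -0.39, adjusted p = 0.679), between Birc5 and Rbms3 (-1.49 ± 0.16). Of 25 cathepsins and lysosomal genes 4 rose and 12 fell (median -0.26, adjusted p = 0.489), between the cathepsin Ctsf (1.59 ± 0.20, detected on 2 of 3 hypoxic arrays) and the peptidase Tpp1 (-1.79 ± 0.15). Counts of the last 5 lists were the same adjusted over the list alone. Of 17 endothelial markers 3 were measured (Flt1, Tek and Egfl7), with Egfl7 at 1.62 ± 0.15 (0.19 on another probe, adjusted p = 0.524) and the receptor Flt1 at -1.17 ± 0.13. Of 14 adipocyte markers, 12 with a named probe, 2 were measured, of which the transcription factor Cebpa was at least 1.91-fold lower and Lpl did not pass.

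With camera's preset correlation 11 of 24 lists passed, 7 up and 4 down. With an estimated correlation 0 passed (adjusted p 0.114 to 0.539 for those 11), and fry, which asks only whether a list's genes move on balance one way, called 19. The 11 calls were also made with the sets as a block.

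The second comparison asked what had changed over the first 3 days in normoxic conditions. Mmp14 was already lower, having fallen by 1.06 ± 0.13 (2.08-fold, adjusted p = 0.000369) with 3 of 3 early arrays below the hypoxic ones. Mitotic and DNA replication genes rose almost throughout, whereas HIF, ATF4, lysosomal and interferon-response genes were mostly lower. With an estimated correlation none of these list calls held (adjusted p 0.161 to 0.367), not even with 25 of 25 mitotic genes rising. With 4 residual degrees of freedom that test has little power and does not decide them. The chemokine gene Ppbp rose at least 164-fold, not being above background on any hypoxic array, and Prelp fell furthest (-6.70 ± 0.28).

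In all 5687 genes (54.9%) passed, 2657 higher and 3030 lower, and 2668 of them by at least 2-fold. With the sets as a block 5389 passed, and within set b, which holds days 1 to 3 with hypoxic replicates 1 and 2 and takes its spread from those 2 alone, 5392. Set a holds no early array. Beyond Ppbp the largest rises were of the kallikrein protease Klk6 (7.43 ± 0.12), the cytokine Il24 (6.87 ± 0.26, detected on 2 of 3 hypoxic arrays) and Prl2c4 (6.69 ± 0.33), a near-identical paralog of Prl2c3. Klk6 stood at 14.36, 13.62 and 11.56 on days 1, 2 and 3, a spread that its SE does not hold. The largest falls after Prelp were of Wfdc3, a protein with a protease inhibitor domain (-6.01 ± 0.14), Gsta3 (-5.62 ± 0.23, another probe at -0.28, adjusted p = 0.419) and the interferon-inducible Ifi27l2a (-5.60 ± 0.57). Of the 3 early arrays, 2 detected Prelp, Wfdc3 and Gsta3 and 1 detected Ifi27l2a. Adjusted p for these 8 genes ran from 5.43e-07 (Klk6) to 0.000181 (Ifi27l2a).

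Among metalloproteases, 9 of 23 rose and 4 fell (10 and 5 adjusted over the list alone, median 0.25, adjusted p = 0.156). Timp1 rose by 4.42 ± 0.18, Mmp3 by 3.78 ± 0.18 and Adam12 by 2.40 ± 0.24. Mmp10 rose at least 5.05-fold and Mmp9 at least 1.58-fold (adjusted p = 0.0202). Besides Mmp14 the falls were of Mmp11 (-1.91 ± 0.26), Mmp13 (-1.71 ± 0.30) and the sheddase Adam9 (-0.64 ± 0.16). Mmp13 varied between the early arrays, at 9.46, 6.90 and 8.56 on days 1, 2 and 3 against a hypoxic mean of 10.01.

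Of 25 mitotic genes 25 rose (median 2.70, adjusted p = 7.33e-14, adjusted p = 0.161 with an estimated correlation), likewise adjusted over the list alone. Of 33 replication genes 32 rose (33 adjusted over the list alone), at a median of 2.56, or 2.40 with members at their bound (adjusted p = 4.42e-15, adjusted p = 0.163 with an estimated correlation). HIF targets fell in 19 and rose in 3 of 25 cases, likewise adjusted over the list alone (median -1.64, adjusted p = 3.31e-05, adjusted p = 0.161 with an estimated correlation). Glycolysis genes fell in 10 and rose in 1 of 16 (11 and 1 adjusted over the list alone, median -0.77, adjusted p = 0.00164, adjusted p = 0.163 with an estimated correlation). ATF4 genes fell in 24 of 28 with 0 rising, likewise adjusted over the list alone (median -1.58, adjusted p = 5.27e-07, adjusted p = 0.321 with an estimated correlation), and chaperones in 16 of 20 (17 adjusted over the list alone, median -1.14, adjusted p = 2.52e-06, adjusted p = 0.126 with an estimated correlation). Lysosomal genes fell in 18 and rose in 2 of 25 (18 and 3 adjusted over the list alone, median -0.77, adjusted p = 0.000519, adjusted p = 0.161 with an estimated correlation).

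Interferon-response genes fell in 21 of 29 cases with 0 rising, likewise adjusted over the list alone, at a median of -1.28, or -0.90 with members at their bound (adjusted p = 1.24e-05, adjusted p = 0.367 with an estimated correlation). Sterol genes rose in 11 and fell in 1 of 18, likewise adjusted over the list alone (median 0.77, adjusted p = 0.00167, adjusted p = 0.215 with an estimated correlation). Epithelial-mesenchymal transition genes rose in 15 and fell in 4 of 24, likewise adjusted over the list alone, at a median of 1.00, or 0.80 with bounds (adjusted p = 0.00136, adjusted p = 0.161 with an estimated correlation). Chemokine and NF-kB targets rose in 16 and fell in 6 of 30, likewise adjusted over the list alone, at a median of 0.60, or 0.40 with bounds (adjusted p = 0.0075, adjusted p = 0.300 with an estimated correlation). These list tests were added after the data were seen. They called 11 lists, also with the sets as a block, and 0 with an estimated correlation. The 13 other lists had adjusted p of 0.0945 to 0.663, of which the metalloprotease, matrix, basal, stem cell and oxidative phosphorylation lists passed, rising, with every probe on its own (0.00344 to 0.0480) and the matrix list without hypoxic replicate 3 (0.0427), and median and mean differed in sign for the luminal list (-0.085 and 0.18) and the stem cell list (-0.036 and 0.77).

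**Figure D3:**
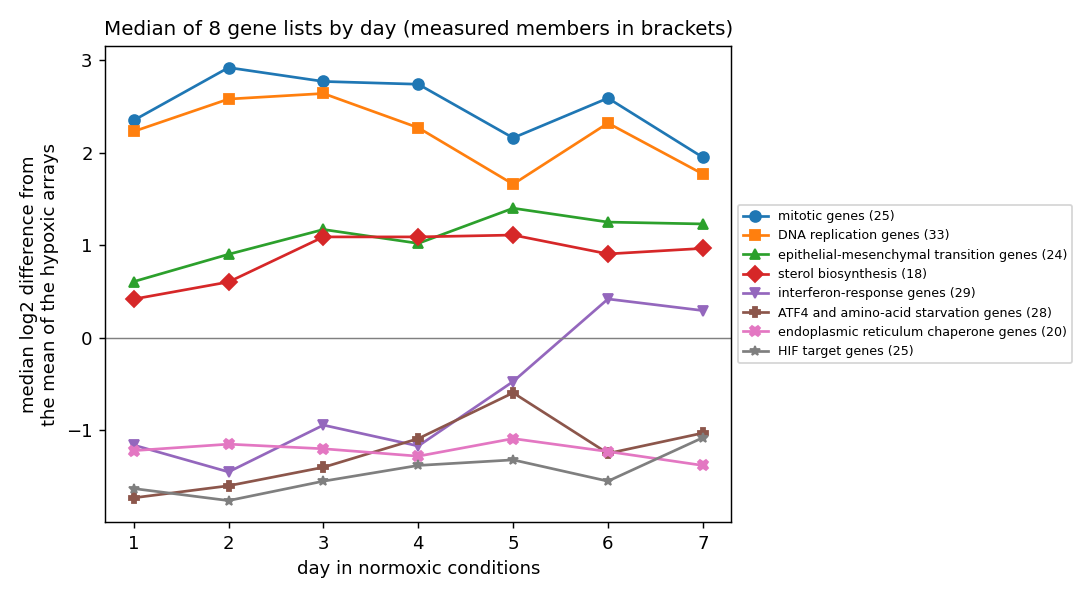
Median log2 difference of 8 gene lists from the mean of the 3 hypoxic arrays (y axis) by day in normoxic conditions (x axis), 1 array per day and the mean of 3 on day 7, with measured members in brackets. The interferon-response list lies at -1.16 on day 1 and 0.29 on day 7, while the mitotic list stays above the other lists on each day.

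Each normoxic array was also set against pairs of hypoxic arrays, without a test. On day 1, 2606 to 2765 genes differed by at least 2-fold over the 3 pairs, on day 5 2277 to 2401, and on day 6 3007 to 3150. The day 7 arrays gave 2978 to 3167, 3324 to 3531 and 3299 to 3465 genes. A left-out hypoxic array set against the other pair gave 65 to 100. On raw signals without background correction the counts were lower by over 1.5 times, at 1563 on day 1, 1276 on day 5 and 1802 on day 6. The interferon-response median was -1.16, -1.45, -0.94, -1.17 and -0.47 on days 1 to 5, then 0.42 on day 6 and 0.29 on day 7.

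The third comparison asked which genes had a linear slope over days 1 to 7 within normoxic conditions, whether or not they changed steadily. Interferon-response genes had the largest median slope of the lists (adjusted p = 8.86e-10, adjusted p = 0.433 with an estimated correlation), and the proteases Asprv1 and Klk7, the surface antigen Psca and the cornified envelope protein Cnfn fell furthest. Mmp14 had a slope of -0.089 ± 0.030 per day (adjusted p = 0.0385). That call ended without the array of day 1, 3, 4 or 6 or without any 1 of the 3 day 7 arrays (adjusted p 0.0562 to 0.137), and with the sets as a block (-0.098, adjusted p = 0.0990).

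The steepest rises per day were of Saa1, a serum amyloid with near-identical paralogs (1.02 ± 0.12), Wfdc3 (0.86 ± 0.10), the ubiquitin-like interferon product Isg15 (0.83 ± 0.09) and Ifi27l2a (0.82 ± 0.16). The steepest falls were of the skin aspartic protease Asprv1 (-1.35 ± 0.09), Psca (-1.23 ± 0.04), Cnfn (-1.16 ± 0.06) and the kallikrein Klk7 (-1.07 ± 0.06). Adjusted p for these 8 ran from 2.22e-07 (Psca) to 0.00380 (Ifi27l2a). Saa1 was not above background on any early array. On day 7, Asprv1 and Psca were each detected on 2 of 3 arrays and Cnfn on 1 of 3. Timp3 fell by 0.23 ± 0.03 per day (adjusted p = 0.000822) and Mmp12 rose by 0.60 ± 0.13 per day (adjusted p = 0.00475).

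**Figure D4:**
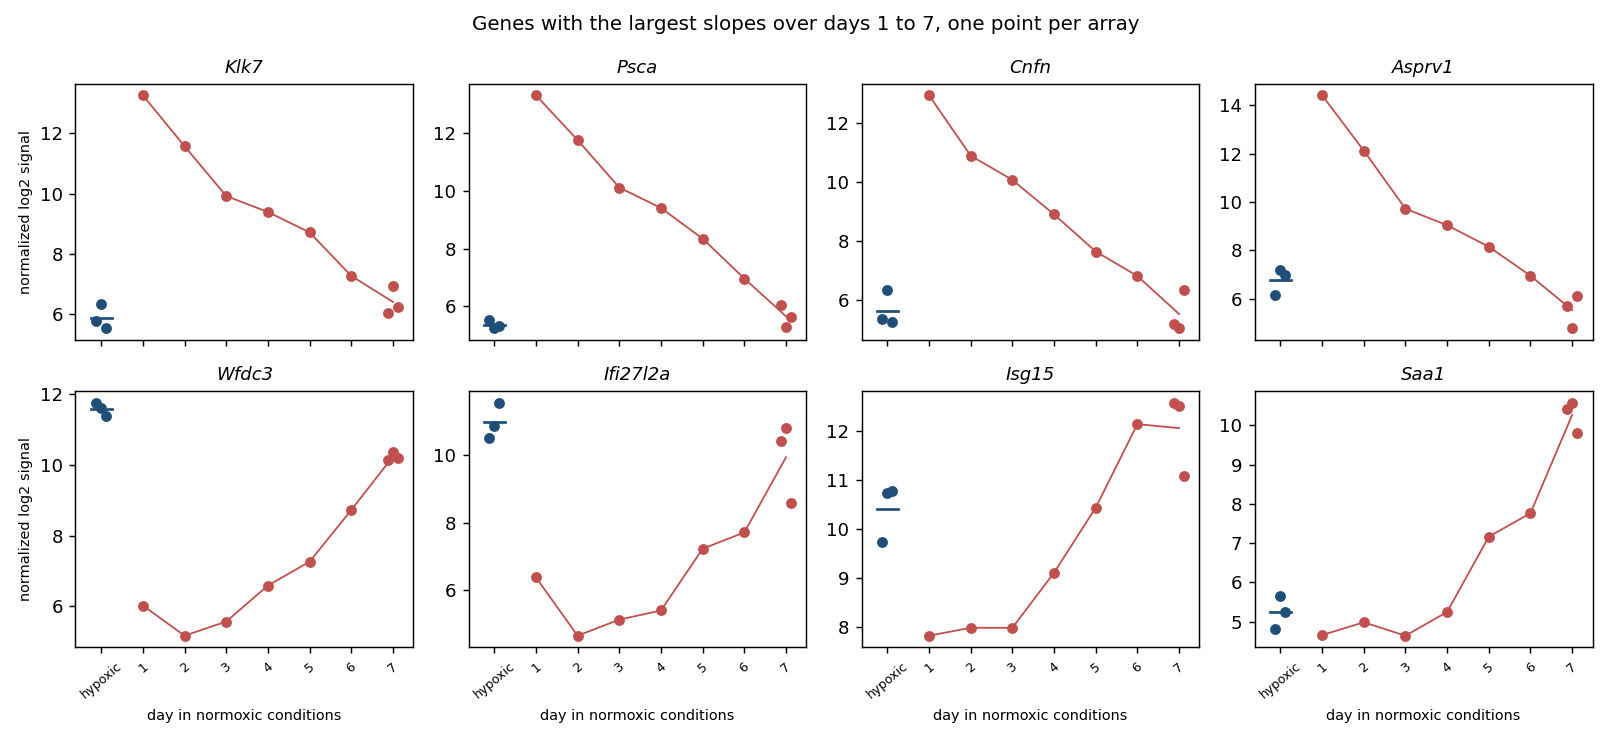
Normalized log2 signal (y axis) of the 8 genes with the steepest slopes, in hypoxic cells (blue) and by day in normoxic conditions (red, x axis), 1 point per array, with bars for the hypoxic mean and lines through daily means. Klk7, Psca, Cnfn and Asprv1 have means of 11.58, 11.72, 11.29 and 12.09 over days 1 to 3 and of 6.41, 5.66, 5.53 and 5.53 on day 7.

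In all 3678 genes (35.5%) had a slope past the threshold, 1709 rising and 1969 falling. The rising share was 46.5%, against 24.6% with arrays shifted to a common median, 56.2% with scaling on probes detected on all arrays and 53.6% with cyclic loess, so which direction held the majority depends on the scaling. Days 1 to 3 lie in set b and days 4 to 6 in set a, so that day and set are partly confounded. With the sets as a block 2096 genes passed, within set a alone 3 and within set b alone 335. With the mean of the day 7 arrays as 1 array 1851 passed.

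Interferon-response genes rose in 21 of 29 cases with 0 falling (22 adjusted over the list alone), at a median slope of 0.36 per day (adjusted p = 8.86e-10, adjusted p = 0.433 with an estimated correlation). Rising medians were also found for oxidative phosphorylation (0.053, 14 of 33 up and 1 down, adjusted p = 0.00212, adjusted p = 0.433 with an estimated correlation), lysosomal genes (0.078, 9 of 25 up, adjusted p = 0.00216, adjusted p = 0.521 with an estimated correlation) and sterol biosynthesis (0.12, 8 of 18 up, adjusted p = 0.00531, adjusted p = 0.521 with an estimated correlation). The same held for ATF4 genes (0.12, 7 of 28 up, 4 adjusted over the list alone, adjusted p = 0.0138, adjusted p = 0.696 with an estimated correlation) and epithelial-mesenchymal transition (0.060, 6 of 24 up and 1 down, adjusted p = 0.0401, adjusted p = 0.433 with an estimated correlation). Falling medians were found for luminal genes (-0.12, 11 of 23 down and 1 up, 13 down adjusted over the list alone, adjusted p = 0.00767, adjusted p = 0.433 with an estimated correlation) and DNA replication (-0.12, 15 of 33 down and 2 up, 18 and 3 adjusted over the list alone, adjusted p = 0.0138, adjusted p = 0.696 with an estimated correlation). Mitotic genes had a median of -0.093 (7 of 25 down and 1 up, adjusted p = 0.0237, adjusted p = 0.696 with an estimated correlation), YAP/TEAD targets of -0.10 (10 of 17 down and 1 up, 11 down adjusted over the list alone, adjusted p = 0.0264, adjusted p = 0.433 with an estimated correlation) and basal genes of -0.078 (9 of 20 down and 1 up, 10 down adjusted over the list alone, adjusted p = 0.0321, adjusted p = 0.433 with an estimated correlation). Counts adjusted over the list alone were otherwise the same. With the sets as a block the basal list was lost (adjusted p = 0.0648) and HIF targets were gained (slope 0.076, adjusted p = 0.0386, against 0.0569). HIF targets also passed with array weights and without day 3, day 6 or day 7 replicate 3 (0.0355 to 0.0498), and stem cell genes, falling, with every probe on its own, without day 7 replicate 3 and with log2 of the day (0.000818 to 0.0489).

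Calls of 4 lists, sterol, basal, transition and ATF4, ended without the day 1 array (adjusted p 0.0883 to 0.212), those of the basal, mitotic and replication lists without day 2 (0.0637 to 0.107) and that of the mitotic list without day 7 replicate 2 (0.0643). With a common median the basal, transition, mitotic and YAP/TEAD calls ended (0.0515 to 0.0848), with that over probes detected on all arrays the basal, transition and YAP/TEAD calls (0.0641 each), and with a detection p under 0.01 the transition and YAP/TEAD calls (0.0572 each). The transition call also ended with the mean over probes (0.0922) and array weights (0.0784), the basal call with array weights (0.0510), and the mitotic call with the day 7 mean as 1 array (0.0849) and log2 of the day (0.0727). The 13 other lists had adjusted p of 0.0569 to 0.935. Glycolysis (median -0.036, mean 0.0017), fatty acid synthesis (-0.047, 0.0011), metalloproteases (-0.0056, 0.017), extracellular matrix (-0.0019, 0.00085), chaperones (-0.012, 0.016) and NRF2 targets (0.0041, -0.026) had medians and means of opposite sign.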

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

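The contrast of day 7 with days 1 to 3 and every set fit were chosen after the data were seen, the tests of immune cells, and of the set for cytokine genes, after values bearing on them had been seen, and the other tests of the set and of single arrays after the patterns but before their own values.

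A difference between time points flagged the following. Between days 1 to 3 and day 7, 4634 genes differed (2082 higher and 2552 lower on day 7, 3295 in all with the sets as a block and 2666 within set b alone, where the spread comes only from 2 hypoxic arrays and the lone day 7 array and the single early arrays are assumed to vary like them), 44.9% of them higher on day 7 against 26.2% with arrays shifted to a common median and 55.4% with scaling on probes detected on all arrays. Mmp14 fell further, with a change of -0.422 (adjusted p = 0.0293), against -0.398 with the sets as a block (adjusted p = 0.114) and -0.144 with scaling on detected probes (adjusted p = 0.399). Medians rose for interferon-response genes (1.78, 21 of 29 up, adjusted p = 1.85e-08, adjusted p = 0.491 with an estimated correlation), ATF4 genes (0.657, 13 of 28 up and 1 down, adjusted p = 0.00678, adjusted p = 0.608 with an estimated correlation), sterol biosynthesis (0.490, 10 of 18 up and 1 down, adjusted p = 0.00229, adjusted p = 0.318 with an estimated correlation), lysosomal genes (0.479, 14 of 25 up, adjusted p = 0.000433, adjusted p = 0.150 with an estimated correlation) and oxidative phosphorylation (0.279, 15 of 33 up and 1 down, adjusted p = 0.00103, adjusted p = 0.150 with an estimated correlation). Medians fell for DNA replication (-0.709, 20 of 33 down and 3 up, adjusted p = 0.00491, adjusted p = 0.530 with an estimated correlation), mitotic genes (-0.593, 15 of 25 down and 1 up, adjusted p = 0.00103, adjusted p = 0.491 with an estimated correlation), luminal genes (-0.588, 12 of 23 down and 1 up, adjusted p = 0.0110, adjusted p = 0.261 with an estimated correlation) and YAP/TEAD targets (-0.498, 11 of 17 down and 2 up, adjusted p = 0.0394, adjusted p = 0.318 with an estimated correlation). Counts adjusted over the list alone were the same, save sterol biosynthesis with 11 up and oxidative phosphorylation with 16 up and 2 down. All 9 calls were made with the sets as a block. Without day 1 the sterol (adjusted p = 0.0673) and ATF4 (0.0511) calls ended. The YAP/TEAD call ended with a common median (0.103), with scaling on detected probes (0.0934), with a detection p under 0.01 (0.0764), and without day 3 (0.0503) or day 7 replicate 2 (0.0640). Calls were also gained under single alternatives. Basal genes, falling, passed among others with raw signals and without day 3 (0.0196 to 0.0483). HIF targets, rising, passed without a detection filter, day 3 or day 7 replicate 3 (0.0266 to 0.0483), and stem cell genes, falling, with every probe on its own (0.00186).

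A signal outside the genes analysed flagged the probes without a single gene name. Of 2538 such probes kept, 1298 passed the threshold for day 7 against hypoxic cells, 600 higher and 698 lower.

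Genes highest on days 1 to 3 numbered 880, with a median rise of 1.16 over hypoxic cells and a later median change of -0.933. All early arrays lie in set b, so a difference between the sets was weighed as their source. Between the sets these genes differed by 0.0176 of that rise in hypoxic cells and by 0.0354 on day 7, far below the 0.5 that a set difference would need, although calling itself favours genes with little spread inside groups. With the sets as a block, 490 genes were highest on these days. A passing response to the change of medium and oxygen remains an untested hypothesis, and each early day has 1 array.

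Interferon-response genes were lower on days 1 to 3 than on day 7 by a median of 1.78 (adjusted p = 1.85e-08, adjusted p = 0.491 with an estimated correlation). Between the sets the list differed by 0.109 of this in hypoxic cells and, in the opposite direction, by -0.227 on day 7. Without day 7 replicate 1, the array whose omission lowered the median most, 0.811 of it stayed (median 1.44). Macrophages and lymphocytes on day 7 are a poor account of it, since of their 28 markers a share of 0.0357 (1 gene, Cd14) was above background on all day 7 arrays. Of Lyz2, Tyrobp, Fcer1g, C1qa and C1qb none was measured, so no rise of theirs could be called. Markers of granulocytes were not tested, so other immune cells stay open for the later rise. Cells present only on day 7 would not account for the early fall below hypoxic cells, where 21 of 29 members fell and 0 rose. A change inside the tumour cells over days in culture remains open as a hypothesis found and tested on the same data. The median of 1.78 was not taken with members at their bound, although some, such as Ifi47, were not above background on any early array. For days 1 to 3 against hypoxic cells such bounds moved the list's median from -1.28 to -0.90.

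Cytokine and acute-phase genes were among the largest rises on day 7, a group named after values were seen. Saa3 rose by 6.28, Ccl9 by 5.47, Il6 by 5.19, Ccl2 by 5.08, Saa1 by 5.02 and S100a9 by 4.84. The same share of 0.0357 of macrophage and lymphocyte markers on day 7 argues against those cells as their source, and Lyz2 was detected on 1 of 3 day 7 arrays. Granulocytes were not tested. Between the sets these genes differed by 0.021 of their median rise of 5.13, with the same favour for small spread, and both sets hold arrays of either group. Cells like fibroblasts were not tested as a source and stay open, as does the change of medium and oxygen. Of 9 fibroblast markers 6 rose on day 7 (median 0.80). Their medians over hypoxic cells were 0.344, 0.995 and 0.928 on days 1, 2 and 3. The list test of days 1 to 3 against hypoxic cells was not passed (4 of 9 up and 1 down, camera adjusted p = 0.113). From days 1 to 3 to day 7 their median changed by 0.172 and their mean by 0.549 (camera adjusted p = 0.193). These list tests thus do not settle when the markers rose. Dcn, 1 of them, rose only after the early days like Saa1 (6.63 in hypoxic cells, 6.64 on days 1 to 3, 10.4 on day 7).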

How the results depend on the processing

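The shift to a common median over detected probes, background fitted without detection p-values and all fits with the inferred sets were chosen after the data were seen, as were the contrast of day 7 with days 1 to 3, the list tests of days 1 to 3 and the genes highest or lowest on days 1 to 3. Of the main results' values under alternatives, 276 stayed on their side of the threshold or near their count, 28 moved and 19 became weaker. Of list values 1999 stayed, 76 became weaker and 61 stronger, with 0 called lists reversed. Of named-gene values 1756 stayed, 20 became weaker, 19 stronger and 3 reversed. Those 3 came from another probe of Sfn (-0.0968), Adam12 (-0.236) and Timp3 (0.349). Mmp14 kept its call on day 7 and on days 1 to 3 under every alternative run for it (adjusted p up to 0.000921 and 0.00263). Where a value below moved, the cause was not tested, save that a 2-fold limit can only remove genes.

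Genes for day 7 against hypoxic cells numbered 3084 with a 2-fold limit and 2626 in set a alone. Genes of the trend numbered 2096 with the sets as a block, 1851 with the day 7 mean as 1 array, 335 in set b alone and 3 in set a alone, and those of day 7 against days 1 to 3 numbered 2666 in set b alone. Genes highest on days 1 to 3 numbered 490 with the sets as a block, and genes lowest 478, or 483 with a common median. With an estimated inter-gene correlation 0 lists passed in any comparison, fry called 19 on day 7, 22 on days 1 to 3 and 17 for day 7 against days 1 to 3, and 7 passed for the trend with a common median.

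On raw signals with quantile normalization and no background correction, genes at 2-fold or more on days 1 to 6 numbered 1563, 1862, 1724, 1648, 1276 and 1802, and on the day 7 arrays 1789, 2048 and 2016 (main medians 2681, 3067, 2942, 2955, 2399 and 3121, then 3121, 3473 and 3447).

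The Mmp14 trend lost its call with cyclic loess (-0.0804, adjusted p = 0.0515), scaling on detected probes (-0.0393, 0.285), array weights (-0.0790, 0.0615), the sets as a block (-0.0975, 0.0990), the day 7 mean as 1 array (-0.0848, 0.155) and log2 of the day (-0.200, 0.0739), over a range of adjusted p from 0.0123 to 0.285. For day 7 against days 1 to 3 it lost its call with cyclic loess (-0.371, 0.0505), detected probes (-0.144, 0.399) and the sets as a block (-0.398, 0.114), over a range from 0.00123 to 0.399.

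With each array left out in turn, genes passing ranged from 5485 to 5943 (day 7), 4990 to 5355 (days 1 to 3), 2723 to 3750 (trend) and 3814 to 4432 (day 7 against days 1 to 3), and lists from 11 to 12, 11 to 12, 7 (without day 1) to 13 and 7 to 10. Genes highest on days 1 to 3 ranged from 609 to 868 and lowest from 530 to 771. Mmp14 ranged from -1.537 to -1.401, -1.163 to -0.955, -0.1104 to -0.0758 and -0.525 to -0.317, losing the trend call without day 1 (0.137), 3 (0.0631), 4 (0.0575) or 6 (0.0631) or day 7 replicate 1 (0.0723), 2 (0.105) or 3 (0.0562), and the last call without day 1 (0.112) or day 7 replicate 1 (0.0579) or 2 (0.0863).

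With the replicate number as a block, 6000 genes passed on day 7 (5818 of the 6184), 11 lists, and Mmp14 at -1.48 (adjusted p = 0.000921). Arrays of the same number correlated at 0.029, -0.0037 and 0.0589, within the -0.11 to 0.0775 of all pairs, so no pairing by number was seen. So few correlations of deviations from group means cannot show whether arrays of the same number were handled together. The authors' processed values and the chip barcode as a block, both planned, were not run, the first because that table holds signals of only 6 arrays and the second because no barcode was given in the sources used here. If the inferred sets are chips, which no label states, the fit with the sets as a block stands in for the second. Signal over background limits what can be seen, with 34.3% to 37.7% of probes detected per array.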

Other observations

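The genes highest or lowest on days 1 to 3 and the test of gene families were chosen after the data were seen; the counts over other splits of the arrays were planned.

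Many members of gene families that include genes of the cornifying epidermis were higher, as a mean over days 1 to 3, than in hypoxic cells and on day 7. Of 46 measured members of the Klk, Krt, Lce, Serpinb and Sprr families, which hold kallikreins, keratins, envelope proteins and protease inhibitors, 28 (60.9%) were highest on days 1 to 3, against 852 of 10319 other genes (8.26%, odds ratio 17.3, Fisher's exact test, 2-sided p = 4.35e-19). Genes are not independent and the families were picked from the top genes, so an excess was built in and this p is no evidence for it. Klk7 changed by 5.69 and then by -5.17, Krt16 by 5.73 and -3.58, Sprr1b by 5.13 and -4.86 and Krt90 by 5.50 and -5.48, and near-identical relatives leave the source of the Krt90, Sprr, Lce and Serpinb signals uncertain. Krt75 (-1.63, then 1.47) and Sprr2a1 (-1.46, then 0.96) were lowest on days 1 to 3 instead. Outside these families, Krtdap, a keratinocyte differentiation peptide, rose by 6.57 and fell by 2.46, Psca rose by 6.34 and fell by 6.06, and Cnfn rose by 5.64 and fell by 5.76. Psca was detected on 1 of 3 hypoxic and 2 of 3 day 7 arrays. Cnfn was detected on 1 of 3 hypoxic and 1 of 3 day 7 arrays. Their low ends thus lie near background, and the sizes of their changes are uncertain. These genes were chosen after their values were seen. By day, Klk7 stood at 13.26, 11.57 and 9.92 and Psca at 13.3, 11.75 and 10.11 on days 1, 2 and 3. Their highest values, like those of Klk6 and Cnfn, lay on the single day 1 array. The 28 family members also include Krt7 and Krt8, which the luminal list holds.

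In all 880 genes were highest on days 1 to 3, 285 of them by at least 2-fold on both sides, and 768 were lowest, 276 of them by at least 2-fold on both sides, with a median fall of 1.27 and a later rise of 1.01. With the sets as a block the counts were 490 and 478, and with a common median 1212 and 483. Lists with most members among the highest were DNA replication (17 of 33) and mitotic genes (14 of 25). Among the lowest were interferon-response (15 of 29), ATF4 (13 of 28), lysosomal (9 of 25), p53 (9 of 24) and HIF target genes (8 of 25).

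For day 7 against hypoxic cells the 10 splits of 6 arrays are too few for a share under 0.05, and the real split, 1 of the 10, gave 6184 genes and the highest other split 0. The same holds for days 1 to 3 against hypoxic cells, where the real split, 1 of the 10, gave 5391 genes in a 2-group fit and the highest other 0. Of 100 orders of the days over the 9 normoxic arrays only 1, the real order, gave as many genes as the 3678 observed, and the highest other gave 2434. These orders treat the 9 arrays as exchangeable, ignoring the inferred sets and the 3 day 7 replicates, and the trend had 2096 genes with the sets as a block and 1851 with the day 7 mean as 1 array.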
